A study of Mus musculus with 12 samples.

How the data were processed

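Liver poly(A) RNA of 12 female C57BL/6J mice was sequenced as strand-specific paired-end libraries, with 1 library per animal as the labels read and 4 libraries in each of 3 groups (control, DHT, DHT plus baicalin). The deposited table holds 33084 genes by Ensembl mouse identifier. Its counts, as deposited by the authors, are whole numbers per gene and library and not scaled to a common total; whether they count reads or read pairs is not stated. Its FPKM values, as deposited by the authors, are fragments per kilobase of transcript, scaled to the mapped fragments of each library. The submitters' notes name fastp, StringTie and edgeR without versions; the aligner, genome build and annotation are not given in the sources used here, so no coordinates are printed. Symbols were taken from the GENCODE mouse gene table at hand, which matched 30869 identifiers; 34 identifiers with a symbol shared by more than 1 gene keep their identifier.

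Total counts per library ran from 54469990 to 80479692. The main analysis used the counts in edgeR 4.0.16 under R 4.3.3, with limma 3.58.1, DESeq2 1.42.0, matplotlib 3.10.9 for figures and the R package data.table (version 1.17.8). Genes were kept by filterByExpr on the 3 groups (18647), libraries were scaled with TMM factors, and all 12 libraries entered 1 quasi-likelihood fit with 9 residual degrees of freedom. Each of the 3 comparisons used the quasi-likelihood F-test with Benjamini-Hochberg adjustment over all genes, and a gene was called changed at an adjusted p under 0.05. Every adjusted p for a gene comes from this test unless another is named. CPM are counts scaled by the TMM-adjusted library size, and folds against a group with 0 counts in all libraries are bounds against 3 counts over the group. No library was left out of the main analysis.

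37 gene lists (sex-biased liver genes, lipid, glucose, bile acid and xenobiotic metabolism, stress, inflammation, cell type and organelle markers) were written before the data were examined, as were the tests, the thresholds, the other settings tried and the rule for naming genes. Lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, for the 36 lists with enough tested members, with Benjamini-Hochberg adjustment over lists within a comparison. Members called over all genes are counted beside members called when adjusted over the list alone. The text may name, per comparison, the 6 genes with the largest rise and the 6 with the largest fall among called genes without overlap between groups and with at least 1 CPM, up to 4 members of each list by smallest p, a fixed set of androgen, lipid, glucose, xenobiotic, inflammation and collagen genes in every comparison, and the 10 genes with the strongest calls of opposite sign in DHT versus control and DHT plus baicalin versus DHT. A gene named outside this rule is said to be so.

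The number of genes called in both comparisons with opposite signs was set beside 20 simulated data sets without a baicalin effect, the 6 ordered ways to split the 4 DHT libraries between both comparisons, and the overlap expected of independent sets. Calls were tested on simulated data with the depth and dispersion of these libraries, in which 100 genes per fold were changed: 34% of 2-fold and 58% of 4-fold changes were called in DHT versus control, 26% and 63% in DHT plus baicalin versus DHT, and 30% and 52% in DHT plus baicalin versus control, with 4.17%, 3.26% and 1.20% of calls false. The simulated counts were drawn independently per gene and library from a mean over all libraries. They hold none of the library sets described in the results, so their shares of false calls do not carry over to the real libraries. Replicates were checked for copies, and the lowest chi-square per gene between 2 libraries of a group was 30.8, against 1 for sampling noise alone.

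The other settings chosen at that time were RLE or upper-quartile factors, DESeq2, limma-voom, limma-trend on log2 FPKM plus 1 or plus 0.1 (genes with at least 0.5 FPKM in 4 libraries), no filter or a mean of at least 1 CPM, the 10 most abundant genes left out, only the 2 groups compared, the replicate number as a replicate block, 3 other thresholds, and each library left out in turn. After the data were seen, the presence of Y-linked counts (a sum of at least 10 over Ddx3y, Eif2s3y, Kdm5d and Uty) was tried as a covariate, as were fits without the libraries labelled control 4 and DHT plus baicalin 3, without these and DHT 1, and with only the libraries without Y-linked counts. Marker lists of heart, kidney, lung, skin, skeletal muscle, testis and brain were also written after the Y-linked counts were seen.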

Results

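Liver RNA from 12 female C57BL/6J mice was measured by poly(A)-selected, strand-specific, paired-end RNA sequencing, with 1 library per animal as the labels read, in 3 groups of 4. From 3 weeks of age, control mice carried empty silicone tubes under the skin for 12 weeks. DHT mice carried tubes holding 10 mg of dihydrotestosterone (DHT), an androgen that is not converted to oestrogen, replaced every 4 weeks, which the labels call a model of polycystic ovary syndrome with fatty liver disease. DHT plus baicalin mice carried the same DHT tubes and received baicalin, a plant flavonoid, by mouth at 200 mg/kg per day from week 5 for 8 weeks. Libraries held 54469990 to 62423087 counts in control, 56488914 to 69568602 in DHT and 68938063 to 80479692 in DHT plus baicalin. Of 33084 genes in the table, 18647 were tested. Levels below are CPM (counts normalised and scaled to a common library total), as mean ± SD over n = 4 animals per group. The standard error (SE) of a log2 fold change was taken from the edgeR fit as the log2 fold change over the square root of its F value, an approximation.

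The libraries formed 2 sets that cut across the groups. Control 1 to 4 and DHT 1 held 361 to 579 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and the other 7 libraries held 0, which allows up to 0.0103 CPM in the 4 DHT plus baicalin libraries together. Xist, the RNA of the inactive X chromosome, stood at 436 to 746 CPM in all 12 libraries. The same 5 libraries carried transcripts of other organs, read from marker lists written after the Y-linked counts were seen. Their summed heart markers reached 84.0 to 336 CPM against at most 1.73 CPM in the other 7, kidney markers 17.9 to 594 against at most 1.03, and skin markers 76.4 to 212 against at most 4.76. Lung markers reached 51.2 to 81.7 CPM in control 2, control 3 and DHT 1, and 2.89 to 5.83 CPM in the other 9 libraries. The first principal component, with 67.5% of the variance, parted these 5 libraries from the other 7, and genes with at least 1 count numbered 23142 to 23878 in the 5 and 21084 to 22638 in the 7.

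**Figure D1:**
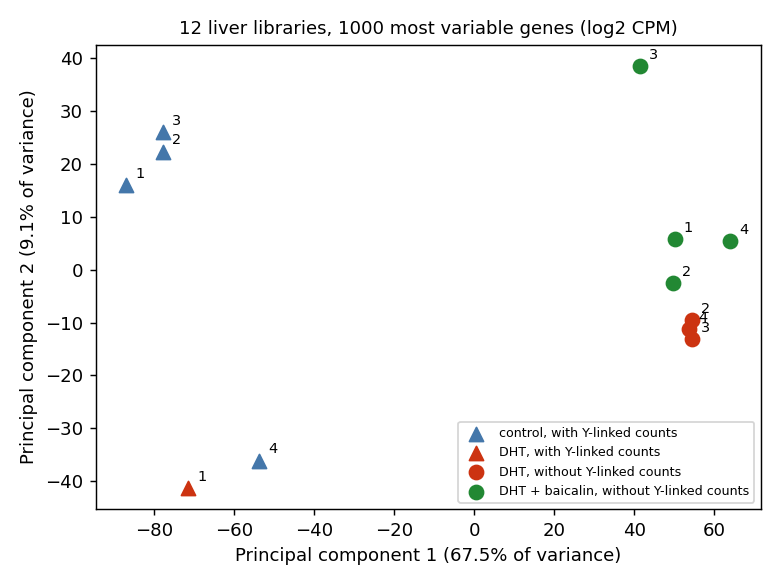
Each point is a library on the first (x axis) and second (y axis) principal component of log2 CPM of the 1000 most variable genes, coloured by group, with its replicate number; triangles hold Y-linked counts and circles hold none. The 4 control libraries and DHT 1 lie apart from the other 7 on the first component, which holds 67.5% of the variance.

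**Figure D2:**
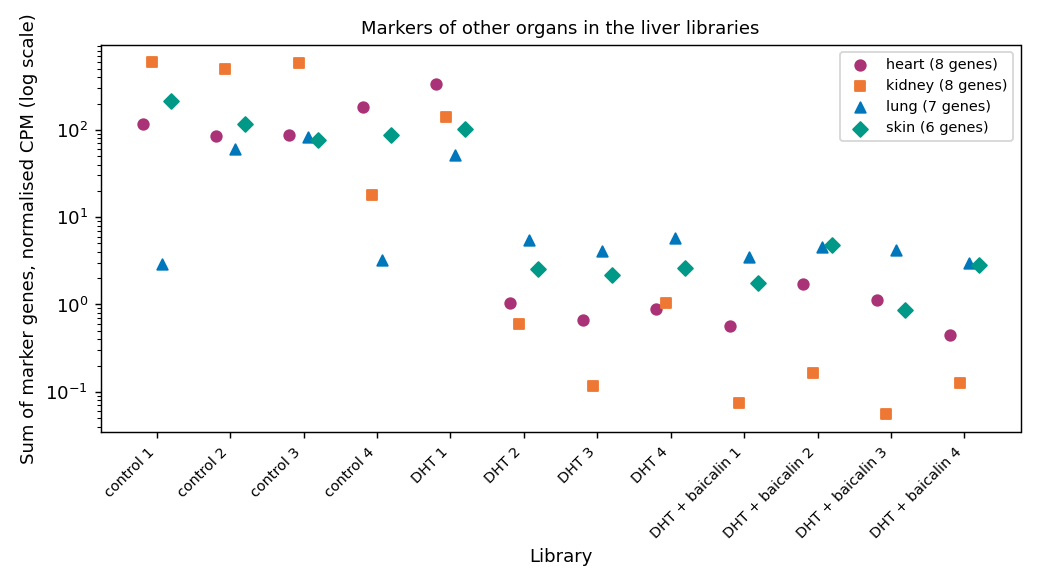
Summed CPM (y axis, log scale) of marker genes of heart, kidney, lung and skin in each of the 12 liver libraries (x axis). Heart, kidney and skin sums in control 1 to 4 and DHT 1 lie above those of every other library, with the lowest kidney sum of the 5 at 17.9 CPM and the highest of the other 7 at 1.03 CPM.

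A different pair of libraries departed from its groups in the genes that differ between male and female liver. The female-biased list averaged 6.41, 6.60 and 6.45 on the log2 CPM scale in control 1, 2 and 3 and 2.27 in the library labelled control 4. It averaged 1.52, 1.62 and 1.49 in DHT plus baicalin 1, 2 and 4 and 6.13 in the library labelled DHT plus baicalin 3. The male-biased list ran the other way, at 3.39 to 3.58 in control 1 to 3 and 5.39 in the library labelled control 4, and at 5.37 to 5.88 in DHT plus baicalin 1, 2 and 4 and 2.83 in the library labelled DHT plus baicalin 3. All 4 DHT libraries stood at 0.86 to 1.76 for the female-biased list and 6.20 to 6.48 for the male-biased list. Results below are given with these libraries in place, and totals and some list results also without them. Leaving both out kept the call or the lack of it in 93 of 104 named gene and comparison pairs. In that fit 8 more pairs passed and 3 lost their call, and these are not listed by gene.

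DHT versus control asked what androgen exposure did to liver transcripts in female mice. Some genes that are higher in male mouse liver were higher in DHT livers (5 of 24), and some that are higher in female liver were lower (7 of 24). As lists, neither was called with an estimated correlation (adjusted p = 0.576 for each). Hsd3b5 (ENSMUSG00000038092), a male-biased steroid dehydrogenase gene, stood at 42.5 ± 3.48 CPM in DHT and 1.78 ± 2.06 CPM in control, a log2 rise of 4.58 ± 0.88 (SE, n = 4, edgeR quasi-likelihood adjusted p = 0.0271). Cux2 (ENSMUSG00000042589), a female-biased transcriptional repressor, was 21.4-fold lower in DHT (log2 SE 0.57, adjusted p = 0.00756). Srebf1 (ENSMUSG00000020538), which encodes the main transcription factor of fatty acid synthesis, rose 2.27-fold, to 64.7 ± 2.95 from 28.5 ± 6.18 CPM (log2 SE 0.16, adjusted p = 0.00766). Lpin1 (ENSMUSG00000020593), a phosphatidate phosphatase gene of triglyceride synthesis, was 12.9-fold lower, at 18.6 ± 5.65 against 240 ± 106 CPM (log2 SE 0.40, adjusted p = 0.00245).

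In total 496 genes changed at an adjusted p under 0.05, 303 higher and 193 lower in DHT, and 4663 genes had an unadjusted p under 0.05. The smallest adjusted p of all genes was that of Nudt7 (ENSMUSG00000031767), a coenzyme A diphosphatase of peroxisomes, which rose 3.91-fold to 230 ± 22.1 from 58.9 ± 6.48 CPM (adjusted p = 3.94e-05). Of 24 male-biased genes, 5 rose and 0 fell over all genes tested, and 13 rose when adjusted over the list alone, with a list median log2 of 2.26. Among them Cyp7b1, an oxysterol hydroxylase, rose 3.90-fold (adjusted p = 0.0193), and Mup7, a urinary pheromone carrier, rose from 302 ± 467 to 5489 ± 912 CPM (adjusted p = 0.0497), a value made uncertain by reads shared among Mup genes. Cyp4a12a, an arachidonic acid hydroxylase with a close paralog, did not pass at 318 ± 34.8 against 49.7 ± 93.4 CPM (adjusted p = 0.276), with 190 CPM in the library labelled control 4 and 2.00 to 4.45 CPM in control 1 to 3. Of 24 female-biased genes, 7 fell and 0 rose, and 21 fell when adjusted over the list alone, with a median log2 of -4.22 that does not change with members at 0 counts set to the 3-count floor. Cyp17a1, a steroid hydroxylase, was 20.7-fold lower (adjusted p = 0.0135) and Trim24, a nuclear receptor cofactor, 2.74-fold lower (adjusted p = 0.0237). Camera with a preset correlation called both lists (adjusted p = 8.05e-13 for male-biased, 2.32e-15 for female-biased genes), and neither was called with an estimated correlation (adjusted p = 0.576 for each). Without the libraries labelled control 4 and DHT plus baicalin 3, 16 male-biased and 21 female-biased genes changed. With both left out, 12 and 15 changed when the presence of Y-linked counts was added to the fit as a covariate, and 0 and 0 with the covariate and all 12 libraries. In that last fit the list medians were 1.64 and -4.44. With the covariate this comparison sets DHT 1 against the control libraries, so its calls rest on DHT 1 as the only DHT library.

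Genes of lipid and glucose metabolism did not move one way. Of 20 genes of fatty acid synthesis Srebf1 rose and 0 fell (3 rose when adjusted over the list alone), and the list was not called (camera adjusted p = 0.241). Fasn and Scd1, its downstream enzymes, had log2 values of -0.06 and 0.63 (adjusted p = 0.907 and 0.592). Of 33 genes of triglyceride assembly, storage and uptake, 1 rose and 3 fell (1 and 3 over the list alone; camera adjusted p = 0.21), among them Lpin2, 1.79-fold lower (adjusted p = 0.0234). The lipid droplet genes Plin2 and Cidec, at 589 ± 112 against 706 ± 401 and 8.11 ± 3.68 against 36.6 ± 52.7 CPM, and Cd36 and Pparg, with log2 values of -0.68 and 0.35, did not pass (adjusted p = 0.604, 0.119, 0.41 and 0.409). Of 31 PPAR-alpha targets and fatty acid oxidation genes, Fgf21, a liver hormone induced by fasting, was 5.32-fold lower (adjusted p = 0.00986) and 0 rose (2 rose and 4 fell over the list alone; camera adjusted p = 0.189), while Cpt1a and Ppara had log2 values of -0.27 and -0.83 (adjusted p = 0.378 and 0.231). Of 21 glucose and insulin genes 1 rose and 2 fell (3 and 4 over the list alone; camera adjusted p = 0.941), the latter being Foxo1, 2.70-fold lower, and Igfbp1, 4.57-fold lower, both regulated by insulin (adjusted p = 0.0191 and 0.0247). Of 24 cholesterol genes 0 were called and 2 rose over the list alone, and the list was called higher (camera adjusted p = 0.0035, and 0.576 with an estimated correlation).

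Some stress and cell-cycle genes were lower in DHT. Of 17 immediate early and heat shock genes 3 fell and 0 rose (12 fell and 2 rose over the list alone), namely Hsph1, 3.20-fold, Hsp90aa1, 2.12-fold, and Jun, 2.38-fold lower (adjusted p = 0.0191, 0.0394 and 0.0466). Camera called the list lower at an adjusted p of 4.06e-05, and fry at 0.00622, but not camera with an estimated correlation (adjusted p = 0.189). The glucocorticoid-responsive co-chaperone Fkbp5 was 6.93-fold lower (adjusted p = 0.00245). Cdkn1a, an inhibitor of the cell cycle counted in the cell cycle list, was 12.7-fold lower (adjusted p = 0.00756). Of the 20 members 2 fell and 0 rose (3 fell over the list alone; camera adjusted p = 0.0252, and 0.576 with an estimated correlation). Of 18 clock genes Bhlhe41, a repressor, rose 5.55-fold (adjusted p = 0.0315) and 0 fell (3 rose and 1 fell over the list alone; camera adjusted p = 0.214), while Dbp, an output gene of the clock, was at 82.0 ± 26.6 against 16.2 ± 13.9 CPM and Arntl, its activator, at 7.85 ± 1.03 against 16.2 ± 6.57 CPM, neither past the threshold (adjusted p = 0.0799 and 0.063). Ar, the androgen receptor gene, was at 1.49 ± 0.56 against 5.01 ± 5.00 CPM (adjusted p = 0.0863).

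Lists of cell and organelle markers were called by camera with 0 to 2 members changed over all genes, and none of them with an estimated correlation (adjusted p = 0.576 to 0.645). Of 19 fibrosis and stellate cell genes Spp1 was 3.45-fold lower in DHT (adjusted p = 0.0398) and 0 rose (1 fell over the list alone), and Col1a1 was at 20.1 ± 20.3 against 65.9 ± 15.9 CPM (adjusted p = 0.0976), with 50.5 CPM in DHT 1 and at most 10.7 CPM in DHT 2 to 4. Of 10 cholangiocyte genes Spp1 and Krt7, a bile duct keratin, fell, the latter 4.54-fold (adjusted p = 0.0462), and 0 rose (5 fell and 1 rose over the list alone). Camera called lower the fibrosis list (adjusted p = 2.7e-06), cholangiocytes (0.018), inflammation and chemokines (0.0105; 1 of 21 fell), Kupffer cells (0.015; 0 of 18 called), neutrophils (0.018; 0 of 8 called), and muscle, mesothelium and gut (0.0159; 1 of 11 fell). It called higher the nuclear oxidative phosphorylation genes (adjusted p = 5.6e-06; 0 of 25 called, 14 rose over the list alone), the mitochondrially encoded genes (1.77e-05; 0 of 13 called, 10 over the list alone), ribosomal proteins (0.00072; 0 of 16 called), pericentral hepatocyte genes (0.00242; 1 of 16 rose) and hepatocyte secretory genes (0.018; 1 of 15 fell, with a list median log2 of 0.45). Mitochondrially encoded genes held 11.1 ± 2.73% of counts in DHT and 8.19 ± 0.41% in control. With the presence of Y-linked counts as a covariate, added after seeing the data, 7 of the 16 lists called by camera kept their call and direction, namely female-biased, male-biased, immediate early, cholesterol, inflammation, cholangiocyte and cell cycle genes. Ribosomal proteins turned lower with it. Since the covariate leaves DHT 1 as the only DHT library against control, neither kept nor lost calls show which lists follow the Y-linked counts. Of the 8 lists that lost their call, Kupffer cells, neutrophils, mitochondrially encoded, pericentral and oxidative phosphorylation genes kept the sign of their median (-0.37, -0.99, 0.24, 0.14 and 0.02, against -0.66, -1.62, 0.72, 0.47 and 0.51). The medians of fibrosis, muscle and secretory genes changed sign (0.17, 0.56 and -0.22, against -0.80, -0.95 and 0.45).

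The count for DHT versus control rested on single libraries. It rose to 4975 without DHT 1 and fell to 21 without control 1, 45 without control 2, 221 without control 3, 25, 20 and 19 without DHT 2, 3 and 4, and 260 without DHT plus baicalin 4. Without DHT 1, all control libraries and no DHT library hold Y-linked counts and transcripts of other organs. The 4975 therefore cannot be told apart from that division. With the presence of Y-linked counts as a covariate the count was 2, and among the named genes Nudt7 kept its call (log2 1.75, adjusted p = 0.00463). Of the 496 genes 495 kept their direction in that fit, with a median of 0.67 of their log2 size (quartiles 0.49 and 0.87) and an SE 1.41 times as large. Some folds stayed about as large, with log2 values and SE of 1.15 ± 0.24 for Srebf1, 4.40 ± 1.04 for Hsd3b5, -4.43 ± 1.09 for Cux2 and -3.22 ± 0.70 for Lpin1 (without the covariate 1.18 ± 0.16, 4.58 ± 0.88, -4.42 ± 0.57 and -3.69 ± 0.40). Others shrank, as Cdkn1a to -2.60 ± 0.60 from -3.67 ± 0.49 and Jun to -0.64 ± 0.41 from -1.25 ± 0.30. DHT 1 is the 1 library that separates the covariate from the groups here, so the lost calls do not show that the changes follow the Y-linked counts. Nor do kept directions and sizes show the reverse, since the calls passed over genes with DHT 1 apart. Of the 303 higher genes 0, and of the 193 lower genes 1, were at least 4-fold higher in DHT 1 than in DHT 2 to 4. Of all tested genes 5.00% were. Srebf1, Cux2, Lpin1, Cdkn1a, Fkbp5, Nudt7, St3gal5 and Tsc22d1 kept their call without any 1 of the 12 libraries. Each other called gene named for this comparison lost it in 1 to 9 of those fits, in most cases those without control 1, control 2 or one of DHT 2 to 4. Without TMM factors the median gene stood at a log2 of -0.31 in this comparison, against -0.06 with them. On the FPKM scale it stood at -0.16. The share of called genes that were higher was 61.1% in edgeR with TMM factors, 49.4% in limma-voom with TMM factors and 22.1% in limma-trend on log2(FPKM + 1), which also tested other genes (13362), so the gap is not assigned to the scale.

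**Figure D3:**
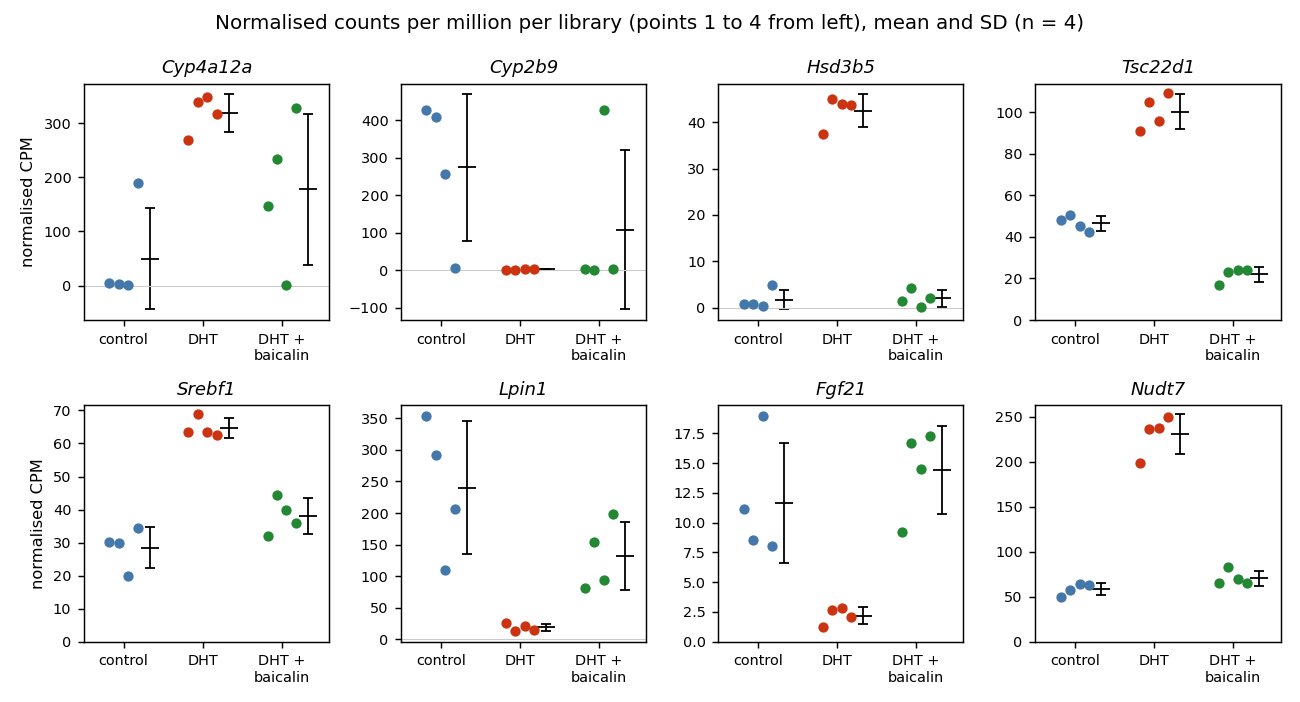
Normalised CPM (y axis) of 8 genes in each library of the 3 groups (x axis), as 4 points per group in replicate order, with the mean and SD beside them (n = 4). Nudt7 and Srebf1 are higher in each DHT library than in every other library, Tsc22d1 has no overlap among the 3 groups, and Cyp4a12a and Cyp2b9 in the libraries labelled control 4 and DHT plus baicalin 3 depart from the rest of their groups.

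DHT plus baicalin versus DHT asked what baicalin changed in DHT-exposed livers. Some genes that stood low in DHT were higher with baicalin. Fgf21 rose 6.56-fold, to 14.4 ± 3.66 from 2.20 ± 0.73 CPM (log2 SE 0.34, n = 4, edgeR quasi-likelihood adjusted p = 0.00557), Lpin1 7.09-fold, to 132 ± 54.2 from 18.6 ± 5.65 CPM (log2 SE 0.39, adjusted p = 0.00736), and Cdkn1a 11.6-fold, to 49.8 ± 19.7 from 4.27 ± 3.13 CPM (log2 SE 0.49, adjusted p = 0.00736). Tsc22d1 (ENSMUSG00000022010), a regulator of the TSC22 family, was 4.55-fold lower, at 22.1 ± 3.63 against 100 ± 8.3 CPM (log2 SE 0.14, adjusted p = 1.95e-05), and Nudt7 3.26-fold lower, at 70.7 ± 8.4 against 230 ± 22.1 CPM (log2 SE 0.13, adjusted p = 9.69e-05).

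In total 210 genes changed, 139 higher and 71 lower with baicalin, and 3724 had an unadjusted p under 0.05. Of 33 genes of triglyceride assembly, storage and uptake 4 rose and 0 fell, Lpin1, Lpin2 (2.27-fold, adjusted p = 0.00591) and the lipid droplet coat genes Plin4 (3.37-fold, adjusted p = 0.0371) and Plin5 (2.51-fold, adjusted p = 0.0283); adjusted over the list alone 4 rose and 4 fell. Camera called this list higher (adjusted p = 0.0316, and 0.502 with an estimated correlation), with a median log2 of 0.07 and a mean of -0.15, which differ in sign. Plin2 and Cidec were at 841 ± 81.1 against 589 ± 112 and 17.8 ± 8.7 against 8.11 ± 3.68 CPM (adjusted p = 0.349 and 0.438), and Cd36 and Pparg had log2 values of 0.55 and -0.22 (adjusted p = 0.57 and 0.676). Of 20 genes of fatty acid synthesis 1 fell, Srebf1, 1.70-fold lower (adjusted p = 0.0429), and 0 rose (2 fell over the list alone; camera adjusted p = 0.368), while Fasn and Scd1 had log2 values of 0.30 and -0.98 (adjusted p = 0.573 and 0.457). Of 31 PPAR-alpha targets and fatty acid oxidation genes Fgf21 rose and 0 fell (2 rose over the list alone), and camera called the list higher (adjusted p = 3.3e-05, and 0.502 with an estimated correlation). Cpt1a and Ppara had log2 values of 0.26 and 0.48 (adjusted p = 0.452 and 0.556). Of 21 glucose and insulin genes Igfbp1 rose 4.01-fold (adjusted p = 0.0409) and 0 fell (5 rose and 2 fell over the list alone; camera adjusted p = 0.0391, and 0.593 with an estimated correlation), and Pck1, of gluconeogenesis, was at 4936 ± 839 against 2969 ± 465 CPM (adjusted p = 0.133).

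Some genes of drug metabolism and stress rose with baicalin. Of 23 CAR and PXR targets 4 rose and 0 fell (5 rose over the list alone), namely Por, the P450 reductase, 2.14-fold, Nr1i2, the PXR gene itself, 1.84-fold, Cyp3a13, 1.81-fold, and Cyp2b10, 8.01-fold (adjusted p = 0.0263, 0.0304, 0.0351 and 0.0499), with the values of both P450 genes made uncertain by reads shared with paralogs. Camera called the list higher (adjusted p = 4.7e-05, and 0.454 with an estimated correlation). Hsph1 rose 2.82-fold (adjusted p = 0.0351), 1 of 17 immediate early and heat shock genes to do so with 0 fallen (8 rose over the list alone). The list was called by camera (adjusted p = 2.02e-05) and fry (0.0247), not with an estimated correlation (adjusted p = 0.121). Dnajb9, a chaperone of the endoplasmic reticulum, rose 1.85-fold (adjusted p = 0.0361), and with Fgf21 made 2 of 20 endoplasmic reticulum stress genes that rose with 0 fallen (8 rose and 1 fell over the list alone; camera adjusted p = 6.95e-05, and 0.454 with an estimated correlation). Fkbp5 and Zbtb16, both responsive to glucocorticoids, rose 3.98-fold and 11.9-fold (adjusted p = 0.013 and 0.025). Of 22 acute phase genes Il1r1, a receptor of interleukin 1, rose 2.04-fold (adjusted p = 0.0461) and 0 fell (8 rose over the list alone; camera adjusted p = 2.84e-07, and 0.454 with an estimated correlation). Of 24 interferon response genes Isg15 was 2.86-fold lower (adjusted p = 0.0374) and 0 rose (1 fell over the list alone; camera adjusted p = 2.02e-05, and 0.564 with an estimated correlation). Of 18 clock genes Arntl and Nfil3 rose 2.65-fold and 2.01-fold, and Dbp and Bhlhe41 were 15.5-fold and 7.76-fold lower (adjusted p = 0.0406, 0.037, 0.0366 and 0.0265; 4 rose and 5 fell over the list alone; camera adjusted p = 0.368).

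Of the sex-biased genes 3 passed, Hsd3b5 and Cyp17a1 toward the control side and Moxd1, a monooxygenase homologue, away from it. Hsd3b5 was 20.8-fold lower with baicalin, at 2.04 ± 1.79 against 42.5 ± 3.48 CPM and in each library (adjusted p = 0.0374), and 2 of 24 male-biased genes fell with 0 risen (5 fell over the list alone). The other was Moxd1, at 0 counts in all 4 DHT plus baicalin libraries, 0.210 CPM in DHT and 0.302 CPM in control. It was at least 20.5-fold lower than in DHT against a floor of 3 counts over the group (adjusted p = 0.0381). Cyp17a1 rose 8.02-fold (adjusted p = 0.0406), 1 of 24 female-biased genes to rise with 0 fallen (14 rose and 1 fell over the list alone). Camera called the male-biased list lower (adjusted p = 4.04e-06, and 0.502 with an estimated correlation; median log2 -0.82) and the female-biased list higher (adjusted p = 2.02e-05, and 0.593 with an estimated correlation; median log2 2.35). Much of the size of the female-biased rise came from the library labelled DHT plus baicalin 3, at 6.13 on the log2 CPM scale. DHT plus baicalin 1, 2 and 4 stood at 1.49 to 1.62 and DHT at 0.86 to 1.76. Without the libraries labelled DHT plus baicalin 3 and control 4, camera still called the female-biased list higher (adjusted p = 0.0161) and the male-biased list lower (2.59e-07). Cyp4a12a stood at 147 to 328 CPM in DHT plus baicalin 1, 2 and 4 and 1.27 CPM in the library labelled DHT plus baicalin 3, against 318 ± 34.8 CPM in DHT (adjusted p = 0.777). Cyp2b9 stood at 1.80 to 2.95 CPM in the former 3 and 426 CPM in the latter, against 2.43 ± 0.80 CPM in DHT (adjusted p = 0.139). Ar was at 8.14 ± 1.51 against 1.49 ± 0.56 CPM, above every DHT library, and missed the threshold (log2 2.45, adjusted p = 0.0565).

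Other cell and organelle lists moved as follows, with DHT 1 the 1 library of this comparison that carried transcripts of other organs. Col3a1, a fibrillar collagen, was 4.22-fold lower with baicalin (adjusted p = 0.0455) and Krt7 5.82-fold lower (adjusted p = 0.0467), each the 1 called gene of its list (19 fibrosis and 10 cholangiocyte genes; 9 and 4 fell over the list alone), and Col1a1 was at 3.19 ± 1.54 against 20.1 ± 20.3 CPM (adjusted p = 0.0545). Camera called lower the cholangiocyte (adjusted p = 7.87e-05), mitochondrially encoded (9.24e-05), fibrosis (0.000333), ribosomal protein (0.017) and adipose tissue (0.0316) lists, and higher the NRF2 target (0.00421), neutrophil (0.0167) and periportal hepatocyte (0.0337) lists. None was called with an estimated correlation (adjusted p = 0.454 to 0.667). With Y-linked counts as a covariate the fibrosis and adipose tissue lists were not called (adjusted p = 0.145 for each), with medians of -0.23 and -0.98 against -1.18 and -5.13. Nor were the NRF2 target (0.0977), periportal (0.12), triglyceride (0.145) and glucose and insulin (0.169) lists, whose medians were 0.23, 0.20, 0.15 and 0.17 against 0.28, 0.22, 0.07 and 0.09. The cholangiocyte, mitochondrially encoded, ribosomal protein and neutrophil lists kept their call and direction (adjusted p of at most 0.0303). In the fit of DHT 2 to 4 against the 4 DHT plus baicalin libraries, all without Y-linked counts, 514 genes changed, 334 higher and 180 lower, of which 169 were among the 210.

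The count for this comparison also rested on single libraries. It was 819 without DHT 1 and 328 without DHT plus baicalin 3, 72, 72 and 347 without control 1, 2 and 3, 32, 29 and 26 without DHT 2, 3 and 4, and 72, 48 and 42 without DHT plus baicalin 1, 2 and 4. With the presence of Y-linked counts as a covariate it was 846, and all 210 genes were among these. That fit, like the one without DHT 1, sets DHT 2 to 4 against DHT plus baicalin, so the 846 is not separate from the 819. Lpin1, Lpin2, Fgf21, Cdkn1a, Nudt7, St3gal5, Tsc22d1 and Slco1a4 kept their call without any 1 library, and each other called gene named here lost it in 3 to 9 of the 12 fits. With upper-quartile factors 55.4% of called genes were higher, against 66.2%.

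Genes called in both comparisons mostly moved in opposite directions. Of the 496 genes changed by DHT, 100 changed the other way with baicalin, 28 higher in DHT and 72 lower, and 1 changed the same way. If both sets of calls were drawn independently, 1.15 and 1.44 genes would be shared in these directions. Besides Nudt7, Lpin1, Cdkn1a, Fgf21, Fkbp5 and Tsc22d1, the genes with the strongest calls in both included St3gal5 (ENSMUSG00000056091), the synthase of the ganglioside GM3, which went from 380 ± 86.3 CPM in control to 108 ± 7.81 in DHT and 313 ± 59.8 with baicalin (adjusted p = 0.00121 and 0.00367). Slco1a4, an organic anion transporter, went from 200 ± 19.1 to 96.5 ± 15.2 and 312 ± 62.5 CPM (adjusted p = 0.0163 and 0.00126). Tsc22d1 passed the control level, from 46.6 ± 3.51 in control to 100 ± 8.3 in DHT and 22.1 ± 3.63 CPM with baicalin. Since the DHT libraries stand in both comparisons, 20 data sets were simulated without a baicalin effect. They gave 0 to 1 opposite genes, but as they called 0 to 1 genes in DHT plus baicalin versus DHT at all, that count does not test the shared libraries. With the 4 DHT libraries split 2 and 2 between the comparisons, the 6 ordered splits gave 2 to 6 opposite genes and 0 that moved the same way. The covariance of both log2 fold changes over all genes was -0.015, against -0.181 to -0.138 in the simulations, and so was not more negative there. Over the splits it was -0.300 to -0.267 with DHT 1 in the pair against control. With DHT 1 in the pair against DHT plus baicalin it was 1.36 to 1.39, so it followed the place of DHT 1. The simulations drew all DHT libraries from a shared mean per gene, so setting the covariance beside them decides nothing. Within the libraries without Y-linked counts all 100 genes kept the direction of their baicalin change and 89 their call. These libraries had also made the calls, so that is no independent repeat. The count was 648 without DHT 1, 12 and 23 without control 1 and 2, 10, 8 and 8 without DHT 2, 3 and 4, and 44, 38 and 29 without DHT plus baicalin 1, 2 and 4. Without DHT 1, Y-linked counts coincide with the labels of DHT versus control, so the 648 cannot be told apart from them. The count was 1 with the presence of Y-linked counts as a covariate, where all 100 genes kept opposite directions and their baicalin call, and 1 kept its DHT call. Their DHT folds were then a median of 0.92 of their log2 size, with Lpin1 at -3.22 and 3.03, Cdkn1a at -2.60 and 4.20, Fgf21 at -3.27 and 2.51, Fkbp5 at -2.40 and 2.15 and St3gal5 at -1.72 and 1.57 in the 2 comparisons. With the covariate the DHT fold sets DHT 1 against control, and the baicalin fold sets DHT plus baicalin against DHT 2 to 4. Called genes seldom had DHT 1 far above DHT 2 to 4, so the selection favoured kept directions and sizes, which decide nothing.

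DHT plus baicalin versus control asked what remained different from control in treated animals. Most changed genes were lower in DHT plus baicalin, among them genes of connective tissue and of epithelia. Col1a1 (ENSMUSG00000001506), a fibrillar collagen gene, was 20.6-fold lower, at 3.19 ± 1.54 against 65.9 ± 15.9 CPM (log2 SE 0.64, n = 4, edgeR quasi-likelihood adjusted p = 0.0197), and Spp1 (ENSMUSG00000029304), the osteopontin gene, 9.64-fold lower, at 31.1 ± 9.14 against 299 ± 136 CPM (log2 SE 0.42, adjusted p = 0.013). Krt1, a skin keratin, was at 0 counts in all 4 DHT plus baicalin libraries and 22.7 ± 14.6 CPM in control, at least 2212-fold lower against a floor of 3 counts over the group (adjusted p = 0.0475), and Umod, a kidney tubule gene, was at 0.0138 ± 0.0275 against 82.5 ± 49.8 CPM (adjusted p = 0.0475). Col1a1, Krt1 and Umod were higher in each control library and DHT 1 than in each of the other 7, and Spp1 was not, at 46.8 CPM in DHT 1.

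In total 170 genes changed, 19 higher and 151 lower, and 3708 had an unadjusted p under 0.05. Of the 151, 26 (17.2%) were at least 4-fold higher in DHT 1 than in DHT 2 to 4, against 5.00% of all tested genes. With only the 2 groups compared, 1204 genes changed, 1053 of them lower. In the fit of all 3 groups used here, a gap between DHT 1 and DHT 2 to 4 adds to the spread and works against calling such genes. The 17.2% therefore does not bound the genes that follow the Y-linked counts, which coincide with the labels in this comparison. Of 19 fibrosis and stellate cell genes 7 fell and 0 rose (14 fell over the list alone; median log2 -1.94), with Col3a1 6.93-fold and Lox, a collagen cross-linking enzyme, 22.6-fold lower (adjusted p = 0.0232 and 0.0352). Of 10 cholangiocyte genes 3 fell and 0 rose (8 fell over the list alone; median log2 -2.47), with Krt7 26.4-fold and Tspan8 6.43-fold lower (adjusted p = 0.0104 and 0.0427). Camera called both (adjusted p = 1.71e-17 and 2.71e-09, and 0.185 for each with an estimated correlation), and fry did (0.0133 and 0.00977). Y-linked counts coincide with the labels in this comparison, so the covariate is set by DHT 1 against DHT 2 to 4 alone. Calls kept, lost or turned with it, here and in the next paragraphs, do not show which lists are free of other organs' transcripts. With the presence of Y-linked counts as a covariate the fibrosis list was not called (adjusted p = 0.535; median log2 -0.09), and the cholangiocyte list was (3.63e-08). Camera also called lower the female-biased (4.87e-07), muscle, mesothelium and gut (3.6e-05), cell cycle (0.000215), adipose tissue (0.00468) and sex chromosome (0.00744) lists, of which 0 members were called over all genes, and 2, 8, 9, 5 and 4 fell over the list alone, where 1 sex chromosome gene rose. Their adjusted p was 0.185 to 0.531 with an estimated correlation. With the covariate the female-biased (0.000731) and cell cycle (0.0276) lists kept their call. The muscle, adipose tissue and sex chromosome lists did not (adjusted p = 0.928, 0.535 and 0.928), with medians of -0.24, -0.18 and 0.24 against -5.40, -5.77 and -9.42. The sex chromosome list had a median log2 of -7.01 with members at 0 counts set to the floor.

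Among higher genes, Mapk15, a protein kinase gene, rose 3.65-fold, Cyp26a1, a retinoic acid hydroxylase, 3.56-fold, and Lrg1, a secreted acute-phase glycoprotein, 2.17-fold (adjusted p = 0.041, 0.0285 and 0.041). Of 23 CAR and PXR targets 0 were called and 11 rose over the list alone, and of 24 cholesterol genes 0 were called and 5 rose over the list alone. Camera called both higher (adjusted p = 7.09e-08 and 4.14e-07, and 0.185 and 0.39 with an estimated correlation). It also called higher the oxidative phosphorylation (adjusted p = 0.00022), acute phase (0.000389), hepatocyte secretory (0.000681), male-biased (0.00071; Moxd1, 1 of 24, fell at an adjusted p of 0.0385), NRF2 target (0.00194), bile acid (0.0139), PPAR-alpha (0.0178), endoplasmic reticulum stress (0.0289) and pericentral (0.03) lists, with adjusted p of 0.277 to 0.618 with an estimated correlation. With the presence of Y-linked counts as a covariate the oxidative phosphorylation list was called lower (adjusted p = 0.039). The other 8 of these and the CAR and PXR list were not called (0.0724 to 0.939), and the cholesterol list was (0.006). Of the lists that lost their call the PPAR-alpha, NRF2 target and male-biased medians were 0.11, 0.23 and 0.78 against 0.09, 0.31 and 1.16. The CAR and PXR, acute phase and bile acid medians were 0.27, 0.22 and 0.08 against 0.51, 0.50 and 0.17. Those of the endoplasmic reticulum stress, pericentral and secretory lists turned to -0.04, -0.21 and -0.23 from 0.26, 0.37 and 0.52. Without TMM factors the median of all genes stood at -0.23 in this comparison, against -0.03 with them, and the list medians of bile acid and PPAR-alpha genes turned negative. Of the 100 genes moved in opposite directions above, Tsc22d1 was the 1 that also passed here, 2.11-fold below control (adjusted p = 0.0104), and it is named for this comparison after its values were seen. Srebf1 and Fgf21 did not pass, at log2 values of 0.42 and 0.30 (adjusted p = 0.167 and 0.642). Fasn, Scd1, Plin2 and Cpt1a had log2 values of 0.24, -0.35, 0.25 and -0.01 (adjusted p = 0.666, 0.819, 0.675 and 0.986). Cyp4a12a, Cyp2b9 and Ar had log2 values of 1.84, -1.34 and 0.70 (adjusted p = 0.512, 0.668 and 0.499).

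Single libraries and the choice of libraries set this count. It was 1691 without DHT 1, 295 without control 4, 6, 0 and 25 without control 1, 2 and 3, 102 and 88 without DHT 2 and 4, and 33, 4 and 10 without DHT plus baicalin 1, 2 and 4. Each gene named as changed lost its call in 1 to 9 of the 12 fits that left out 1 library. With the presence of Y-linked counts as a covariate the edgeR count was 0, with 1137 genes at an unadjusted p under 0.05 (other tools were not run with the covariate). All 170 genes kept their direction in it, with a median of 0.58 of their log2 size and an SE 1.69 times as large. As the covariate is set by DHT 1 against DHT 2 to 4 here, this does not tell the labels from the Y-linked counts. Without the libraries labelled control 4 and DHT plus baicalin 3 it was 432, and 20 of 24 female-biased and 16 of 24 male-biased genes then changed, against 0 and 1 with them.

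Some fixed lists were called by camera in no comparison. In DHT versus control, DHT plus baicalin versus DHT and DHT plus baicalin versus control, in that order, the adjusted p was 0.145, 0.576 and 0.265 for steroid receptors and steroid metabolism, 0.154, 0.888 and 0.157 for AhR targets, and 0.154, 0.0652 and 0.926 for ferroptosis and iron. Fry called the AhR targets lower in DHT versus control and in DHT plus baicalin versus control (adjusted p = 0.0107 and 0.00977, with 8 of 9 members at a negative log2 in each, and 1 risen over all genes in the former), and not in DHT plus baicalin versus DHT (0.98). Camera gave 0.0645, 0.113 and 0.608 for lymphocytes and NK cells, 0.186, 0.136 and 0.942 for erythroid cells, and 0.154, 0.888 and 0.136 for sinusoidal endothelium. Only 1 pancreas gene was tested, too few for a list test, and it was not called over all genes. Median, mean and test differed in sign for 5, 4 and 6 lists in the 3 comparisons, and of these the triglyceride list with baicalin against DHT was the 1 that was called.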

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

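The tests of other organs' RNA, absence of DHT and depth, of a swap and of mixing for the 2 libraries out of place, and of organ RNA and time of day for the genes moved back were chosen after the results were seen; the simulations without a baicalin effect were chosen before.

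Of 189 tests of a library against the other 3 of its group, 30 stood out by a gap above the 95% critical share of the group's range. Chance gives about 5% only for independent tests of normally spread values. Here the CPM were not transformed, the genes were those named in the text, and the same libraries recur. The 30 are therefore listed and not set against that share. DHT 1 accounted for 9, control 3 for 6, the libraries labelled control 4 and DHT plus baicalin 3 for 5 each, DHT 2 for 2, and DHT 3, DHT plus baicalin 1 and DHT plus baicalin 4 for 1 each. The value given for each is the gap to the nearest library as a share of the group's range.

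DHT 1 stood above DHT 2 to 4 in Umod (0.996; 18.5 CPM, nearest 0.0773), Col1a1 (0.966; 50.5, nearest 10.7), Krt1 (0.915; 2.50, nearest 0.214), Lox (0.912; 6.59, nearest 1.00), Cdkn1a (0.902; 8.95, nearest 3.00), Zbtb16 (0.844; 5.03, nearest 1.88) and Col3a1 (0.835; 89.0, nearest 42.0), below them in Hsd3b5 (0.836; 37.3, nearest 43.7), and above them in genes detected (0.97; 23440, nearest 21154). Control 3 stood above its group in Cidec (0.953; 115 CPM, nearest 13.4), Cyp2b10 (0.913; 114, nearest 20.5), Cyp26a1 (0.91; 3.77, nearest 2.04), Plin2 (0.907; 1305, nearest 554) and Plin5 (0.888; 192, nearest 102), and below it in Pparg (0.873; 6.55, nearest 10.5). The library labelled control 4 stood above its group in Cyp4a12a (0.987; 190 CPM, nearest 4.45), Mup7 (0.98; 1002, nearest 77.2), Scd1 (0.925; 6932, nearest 1360) and Hsd3b5 (0.89; 4.86, nearest 0.935), and below it in Umod (0.9; 8.16, nearest 104). The library labelled DHT plus baicalin 3 stood above its group in Umod (1; 0.0550 CPM, nearest 0), Cyp2b9 (0.997; 426, nearest 2.95), Cyp17a1 (0.897; 156, nearest 45.3), Cd36 (0.894; 227, nearest 57.2) and Cux2 (0.834; 7.84, nearest 4.74). The others were DHT 2 in Srebf1 (0.879; 69.1, nearest 63.5) and, lowest, Arntl (0.848; 6.32, nearest 8.18), DHT 3 in Plin2 (0.875; 756, nearest 548), DHT plus baicalin 4 in Hsph1 (0.89; 105, nearest 55.2) and, lowest, DHT plus baicalin 1 in Tsc22d1 (0.876; 16.7, nearest 23.4).

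Transcripts of other organs and of the Y chromosome appeared in control 1 to 4 and DHT 1, and of 29 heart, kidney, lung and skin markers 79.3% were higher in each of these 5 than in each of the other 7. Absence of DHT in control animals is argued against by DHT 1, where the median log2 ratio of these markers to DHT 2 to 4 was 6.15 (quartiles 3.82 and 6.98). Greater depth is argued against by the totals, of which the highest of the 5 (62423087, or 62.4 M) lay below the lowest of DHT plus baicalin (68938063). Mixing of RNA or reads of other organs stays open as a source, since the 29 markers only restate the pattern. Of 10 skeletal muscle and brain markers, 4 parted the libraries in this way, which decides nothing, since mixing need not include those organs. How such RNA or reads came in was not tested, and in DHT plus baicalin versus control it coincides with the labels.

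The libraries labelled control 4 and DHT plus baicalin 3 stood against their labels in sex-biased genes. Mixing of liver RNA of both kinds is argued against, since female-biased genes in the library labelled control 4 had a median log2 ratio of -4.02 to control 1 to 3 (upper quartile -1.18). Whether these libraries were swapped cannot be told apart from other causes: over 33 genes that part the groups, the library labelled DHT plus baicalin 3 lay at a median of 0.19 from control (0) to DHT plus baicalin (1), with quartiles from -0.25 to 0.56, and the library labelled control 4 at 0.06 (-0.15 to 0.28). Other organs' RNA ran with the labels, with 361 and 0 Y-linked counts, heart sums of 183 and 1.11 CPM, skin sums of 86.1 and 0.867 CPM and kidney sums of 17.9 (503 to 594 in control 1 to 3) and 0.0550 CPM in the libraries labelled control 4 and DHT plus baicalin 3, but when that RNA came in is not known, so an earlier exchange stays open. A difference in androgen state between the animals, which DHT treatment makes possible, was not tested and stays open.

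Of the genes changed by DHT, 100 were moved back in the DHT plus baicalin group, and the DHT libraries shared by both comparisons stay open as a cause: the simulations without a baicalin effect gave at most 1 such gene but called at most 1 gene for baicalin at all, and separate DHT libraries gave 2 to 6 opposite genes and 0 that moved the same way, too few to decide. The baicalin change of these genes did not need DHT 1 and its RNA of other organs. In DHT 2 to 4 against DHT plus baicalin, all without Y-linked counts, 89 of the 100 kept call and direction. That holds for these genes only, since the calls had passed over genes with DHT 1 apart. The same libraries had made the calls, so the 89 are no independent repeat. Of the 139 higher and 71 lower genes called with baicalin, 0 were at least 4-fold higher in DHT 1 than in DHT 2 to 4. For the DHT change such RNA cannot be told apart from DHT, because all 4 control libraries and 1 of 4 DHT libraries carry it. The position of DHT 1 (median 0.11, quartiles -0.05 and 0.27, from DHT 2 to 4 at 0 to control at 1) decides nothing. Of 496 called genes, 1 was at least 4-fold higher in DHT 1 than in DHT 2 to 4, against 5.00% of all tested genes. Time of day stays open too, since the median shift of 0.14 (upper quartile 0.29) in the control libraries with high Dbp was taken over genes that had passed DHT versus control, which Dbp itself, with a shift of 0.95, did not (adjusted p = 0.0799). An effect of baicalin remains a hypothesis, since other differences in handling between the groups were not tested.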

How the results depend on the processing

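The settings with the presence of Y-linked counts, and those without more than 1 library, were chosen after seeing the data; the others were chosen before. Values follow the order DHT versus control (496 genes), DHT plus baicalin versus DHT (210), DHT plus baicalin versus control (170) and genes moved in opposite directions (100). Unless said otherwise, the cause was not tested.

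RLE and upper-quartile factors, and leaving out the 10 most abundant genes, kept all 4 counts within 1.5 times. DESeq2 gave 2345, 1493, 1630 and 596. Limma-voom gave 746 for DHT plus baicalin versus control and kept the other 3 within 1.5 times. Without a filter on low counts, where more genes are tested, the counts were 169, 91, 45 and 41, and with a mean CPM of at least 1, where fewer are, 842, 354 and 175 for the first, second and last. With only the 2 groups compared DHT plus baicalin versus control gave 1204. The replicate block gave 928, 92, 313 and 65, although same-number libraries were not shown to be paired, with r of -0.08 to 0.16 in 12 pairs in the replicate block check. Limma-trend on log2(FPKM + 1) gave 1341, 271 and 168, with DHT plus baicalin versus DHT within 1.5 times, and on log2(FPKM + 0.1) 1259, 299 and 169, with the same exception.

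As a covariate, presence of Y-linked counts gave 2, 846, 0 and 1 (edgeR, with 1137 genes at an unadjusted p under 0.05 beside the 0, and no other tool run). Without control 4 and DHT plus baicalin 3 together they were 758, 352 and 432, with the last within 1.5 times, and with the covariate as well 85, 822, 39 and 29. Without control 4, DHT 1 and DHT plus baicalin 3 together they were 4583, 837, 2070 and 557. There Y-linked counts coincide with the labels of DHT versus control, so the 4583 and 557 cannot be told apart from them. With only the libraries without Y-linked counts DHT plus baicalin versus DHT gave 514. At an adjusted p under 0.1 the counts were 2004, 727, 1078 and 369. At an adjusted p under 0.05 and at least 2-fold they were 257, 115 and 47 for the first, second and last, and at an unadjusted p under 0.05 and at least 2-fold 1245, 1420, 1850 and 315. These 3 settings change the threshold by construction.

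Leaving out 1 library at a time gave 19 to 4975, 26 to 819, 0 to 1691 and 8 to 648. The highest were without DHT 1 in all 4, where Y-linked counts coincide with the labels of DHT versus control. The 0 was without control 2, where 3018 genes had an unadjusted p under 0.05 in edgeR and no other tool was run. Of 2052 values computed for 68 called gene and comparison pairs named in the report, 1589 kept direction and call, 463 kept direction and lost the call, and 0 reversed. Of 1093 values for 36 pairs not called, 1010 stayed uncalled, 83 passed and 0 reversed.

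List tests called 16, 18 and 18 of 36 lists in the 3 comparisons. With an estimated correlation 0 were called in each, and fry called 7, 1 and 8. DHT plus baicalin versus control gave 9 with the presence of Y-linked counts as a covariate. The other list counts stayed within 1.5 times under the covariate, the replicate block and the fits without libraries. In the comparisons with control, DHT 1 alone separates the covariate from the groups, so list calls with it rest on that library. With the covariate, these lists took the opposite direction and passed: in DHT versus control sinusoidal endothelium (adjusted p = 0.0103), adipose tissue (0.0103) and ribosomal proteins (0.028), and in DHT plus baicalin versus control oxidative phosphorylation (0.039), mitochondrially encoded genes (0.0306), sinusoidal endothelium (0.00114) and ribosomal proteins (3.39e-08). Without control 4 and DHT plus baicalin 3 and with the covariate, so did sinusoidal endothelium (0.00672), adipose tissue (0.00293) and ribosomal proteins (0.0462) in the former, and mitochondrially encoded genes (0.0487), pericentral hepatocytes (0.000714), sinusoidal endothelium (0.000114) and ribosomal proteins (4.72e-07) in the latter.

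Every library held at least 54469990 counts, and the effect of depth was not tested by thinning them. With 4 libraries per group, calls recovered 26% to 34% of simulated 2-fold changes and 52% to 63% of simulated 4-fold changes, in data simulated without the library sets.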

Other observations

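Libraries without overlap between groups were counted beside the calls. In DHT versus control 2535 genes (13.6%) did not overlap, in DHT plus baicalin versus DHT 1782 (9.56%) and in DHT plus baicalin versus control 2908 (15.6%), where chance gives 2.86%. Testis markers were at 0 in the 5 libraries with Y-linked counts. Tsc22d1 stood at 42.5 CPM in the library labelled control 4 and 24.0 CPM in the library labelled DHT plus baicalin 3, each with its labelled group, but 1 gene excludes nothing.

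Other splits of the same libraries, chosen before the results were seen, asked whether chance can be excluded. For DHT versus control, 2 of 35 splits gave at least the 496 genes of the real split, the other with 1221, so chance cannot be excluded. That other split set control 1, control 2, control 4 and DHT 1 against the rest, and why it called more was not tested. The 3 other splits that put 4 of the 5 libraries with Y-linked counts together gave at most 71. All splits that broke up these libraries further gave 0. Genes were thus called only along that division, though not in each such split, so the test does not separate the count from it. The real comparison gave 2 genes with the presence of Y-linked counts as a covariate, where 495 of the 496 kept their direction at a median of 0.67 of their log2 size and an SE 1.41 times as large. Cux2 (-4.43), Hsd3b5 (4.40) and Srebf1 (1.15) kept about their size. DHT 1 is the 1 library that separates the covariate from the groups, so the fall to 2 does not show that the changes follow the Y-linked counts. Nor do the kept directions and sizes show the reverse, since the calls passed over genes with DHT 1 apart. For DHT plus baicalin versus DHT, 2 of 35 splits gave at least 210 genes, the other with 1356, so chance cannot be excluded. That split set DHT 1 and DHT plus baicalin 1, 3 and 4 against the rest. Splits that set DHT plus baicalin 1, 3 or 4 with DHT 2 to 4, in place of DHT plus baicalin 2, gave 0. Why that split called more was not tested. For DHT plus baicalin versus control, 1 of 35 splits, the real one, reached 170 genes. The highest other gave 115, with the libraries labelled control 4 and DHT plus baicalin 3 in each other's place. That share, 0.0286, is the smallest that 35 splits can give. The real split is also the division by Y-linked counts. The test cannot tell the group labels from that division, and no exclusion of chance is drawn from it. For genes moved in opposite directions, 2 of 35 splits reached 100, the other with 1269, so chance cannot be excluded. That other split was the one that called 1356 genes above, and its cause was not tested. Here a split and its mirror were counted as 1, with the higher of their counts, which was chosen after the result was seen; counted apart, 2 of 70 reached 100. For list tests chance cannot be excluded, since 10, 6 and 9 of 35 splits called at least the 16, 18 and 18 lists of the 3 comparisons, with up to 21, 20 and 23 in the other splits.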
